A study of Homo sapiens with 21 samples.

How the data were processed

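MDA-MB-231 cells with inducible Flag-tagged ER-beta were assayed by ChIP-seq with an antibody against Flag after vehicle, estradiol or LY500307. Per the labels there were 12 ChIP libraries and 9 input libraries, with 4 ChIP and 3 input libraries per treatment, although the protocol text speaks of triplicates. The submitters' processing notes name Bowtie2 2.2.6, MACS2 2.1.1.20160309, DiffBind and the hg38 genome without saying which step each served. The analysis used 3 deposited lists of enriched regions in narrowPeak format, 1 per treatment. The labels of all 4 ChIP libraries of a treatment point to the same list, so each list was taken to describe a pool; whether all 4 libraries went into it is not stated. The single libraries, the inputs on their own and any DiffBind comparison were not analysed here.

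The deposited score of each region is the authors' display score, the integer part of 10 times the -log10 q, and was not used. The fold is, per the labels and the column order, the authors' ratio of pooled ChIP signal over local background at the summit. The deposited -log10 p and -log10 q of each region are those of the authors' peak caller. The summit is the deposited offset in bases from the region start. The authors' lowest deposited -log10 q was 2.02 for vehicle, 2.15 for estradiol and 2.11 for LY500307. All region ends lay within the hg38 sequences.

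Regions on chromosomes 1 to 22, X and Y were kept, which left 2905 of 2911 vehicle, 26861 of 26896 estradiol and 10045 of 10059 LY500307 records. Records of a list that overlapped or touched would have been merged, and none did. The median width was 275 bp for vehicle, 330 bp for estradiol and 302 bp for LY500307, and the median fold was 7.00, 9.50 and 8.46. Positions were converted to 1-based coordinates. Genes, transcripts and promoters came from GENCODE 44, and computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9, with seed 1 for everything random.

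The number of sequenced reads is unknown from the lists. A background pileup was therefore recovered from pairs of deposited fold and -log10 p values, by seeking the whole-number pileup and the local background that give both under a Poisson tail with a pseudocount of 1. The level of a list was the lowest background that still explained a sizeable part of the records explained by the best background. By it, 21.3% of the searched vehicle records, 19.1% of the estradiol and 18.5% of the LY500307 records were explained. The vehicle pileup came in steps of 0.9125, as from a ChIP pool scaled down to its input, so its background was 1.97 in its own fragments. Tested on simulated data, the recovery returned the background without error and the step to within 0.0005 in 3 simulated lists.

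Regions of different lists were called shared when they overlapped by at least 1 bp. Each overlap was compared with 1000 placements of the regions at random positions of the same chromosome outside assembly gaps. Every summit was assigned, in this order of priority, to a promoter (1000 bp upstream to 100 bp downstream of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron or intergenic DNA. Motifs were sought on both strands in the 201 bp around each summit and in a window of equal width 2000 bp downstream, with an exact two-sided sign test on the regions where they differed. The ERE was GGTCANNNTGACC with at most 1 mismatch in its 10 fixed positions, and the other motifs allowed none. The ERE was also sought with no mismatch and with at most 2, and Benjamini-Hochberg adjustment covered all 48 motif tests. ERE shares of overlapping and other regions within a list were compared by two-sided Fisher's exact tests and by Mantel-Haenszel odds ratios within 4 quartiles of -log10 q. Where a cell of such a table was 0, 0.5 was added to each cell for the odds ratio.

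The 12 gene groups, 3 of them controls, were tested by two-sided Fisher's exact tests of genes with a summit within 20 kb of any TSS against all other protein-coding genes, adjusted over 36 tests. Genes and regions are not independent replicates, so these tests speak of positions within a pooled list and not of differences between cultures. In simulated random gene groups 3.0%, 7.0% and 3.67% gave p under 0.05 when 10%, 30% and 55% of genes were near a region. Simulated groups with a large implanted excess gave this in 99.0%, 98.0% and 99.67% of cases. These simulations used a fixed group size, drew genes without regard to position and scored the unadjusted p. They therefore do not give the power or error rate of the adjusted tests. Of implanted EREs, 100% were found in 20000 simulated windows.

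Regions were named by a fixed rule: the 10 with the highest -log10 q in each list, the 10 highest estradiol and the 10 highest LY500307 regions that overlapped no vehicle region, the 5 highest LY500307 regions outside the estradiol list, the 5 highest vehicle regions outside both ligand lists, up to 4 members of each gene group with the highest estradiol region, and ESR2 in all cases. Each was given the protein-coding gene with the nearest TSS. Of the vehicle regions under this rule, 2 on a sex chromosome are not reported here. Further members of the estrogen response group, ESR2 and HDAC7 exon by exon, and the classes of regions in the closing section were chosen after their values were seen. A promoter was assigned to every protein-coding gene whose promoter window held the summit, whichever gene the region was listed for. The coding-exon share of a gene was tested by an exact one-sided binomial test against the coding share of its span, and the p was also multiplied by the 19663 protein-coding genes. Exons with and without a region were compared by permutation of mean exon length and, in a later addition, of mean coding length. The purine-rich word was noticed in a scan of words of 7 bases over several classes of regions; later the word was picked again by a fixed rule on odd-numbered chromosomes and tested on the others, with this 1 split and this 1 word length.

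The alternatives were stricter thresholds (-log10 q of 5 or more, fold of 5 or more), all contigs, records left unmerged, reciprocal overlap of at least 50%, summits within 200 bp, the 2905 strongest regions of each list, promoters of 2500 bp on both sides, no mismatch or 2 mismatches in the ERE, summit windows of 50 bp on each side, dinucleotide-shuffled control sequence, TSS distances of 5 kb and 100 kb, and 10000 random gene groups matched in 25 classes of gene length and gene density. The overlap and annotation alternatives used 100 placements, and reciprocal overlap used 20. The ERE comparison outside promoters was added after the data were seen.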

Results

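Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped where Flag-tagged estrogen receptor beta (ER-beta, encoded by ESR2) sat on the genome of MDA-MB-231 cells, a triple-negative breast cancer line that was given a doxycycline-inducible copy of the receptor. After 24 h of doxycycline at 100 ng/ml, the cells received ethanol vehicle, 1 nM estradiol or LY500307, an ER-beta-selective agonist, for 3 h. The sample titles state 1 nM LY500307, whereas the sample characteristics state 10 nM, so the dose is uncertain. The labels describe 21 libraries, with 4 ChIP and 3 input libraries for each of the 3 treatments. The authors gave 1 list of enriched regions per treatment, to which the labels of all 4 ChIP libraries point. It was read as a pooled list, but the number of libraries pooled is uncertain because the protocol speaks of triplicates. No replicate lists were analysed here, so no value has a replicate error and no difference between treatments was tested. Fold enrichment and -log10 q of a region are the authors' own values for the pool. The pools were scaled separately, so folds of the same site with different treatments stand side by side as values and do not measure a change. Read totals are not in the lists and the sequencing depth is therefore unknown. A background pileup was recovered from the fold and p values of each list instead, and it was 1.00 fragments for estradiol, 1.39 for LY500307 and 1.97 for ethanol (1.80 after the scaling of that pool). All positions are hg38, counted from 1, and all intervals on shares are 95% Wilson intervals that cover counting error only.

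The comparison of the 3 lists asked which sites were found with which treatment. Enriched regions numbered 26861 with estradiol, 10045 with LY500307 and 2905 with vehicle. The estradiol list was 9.25 times as long as the vehicle list and 2.67 times as long as the LY500307 list. LY500307 sites were almost entirely a part of the estradiol sites, because 9230 of 10045 LY500307 regions (91.9%) overlapped an estradiol region. Vehicle sites also recurred with the ligands: 2528 of 2905 (87.0%, 85.8 to 88.2) overlapped an estradiol region and 2317 (79.8%) overlapped an LY500307 region. In the estradiol list, 2151 regions (8.01%) were found in all 3 lists, 6931 (25.8%) were shared with LY500307 alone, and 17442 (64.9%) were in no other list.

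**Figure D1:**
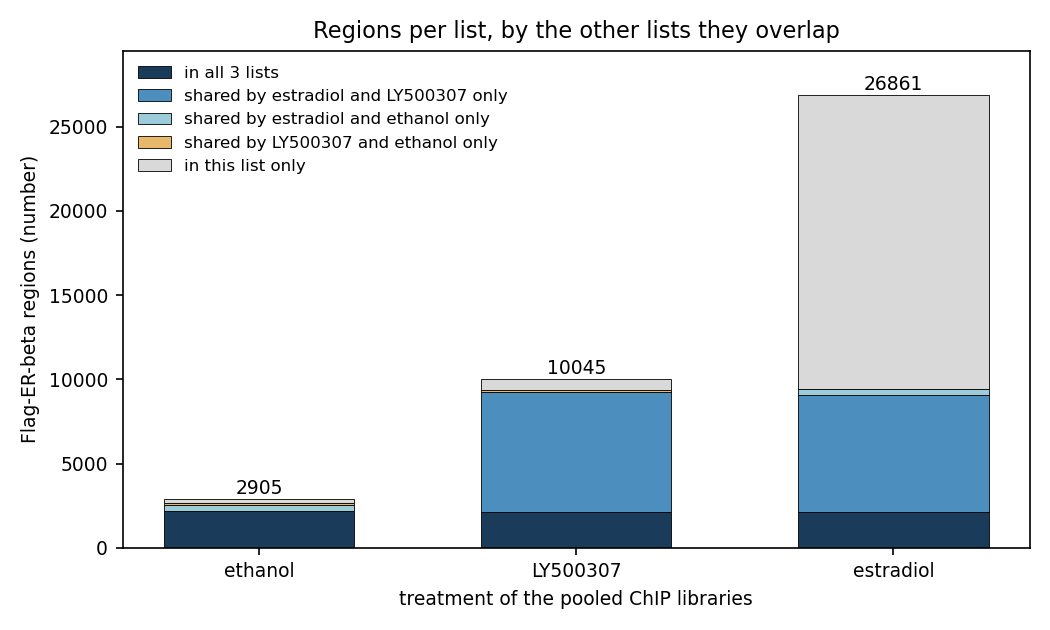
Number of enriched regions (y axis, regions) in each treatment's pooled list, with each bar divided by the other lists that hold an overlapping region. The estradiol bar reaches 26861 regions, of which 17442 lie in no other list, whereas LY500307 reaches 10045 and ethanol 2905.

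The strongest estradiol sites were the ones found with LY500307. All regions in the highest decile of the estradiol list by -log10 q overlapped an LY500307 region (100%), against 9.27% in the lowest decile. The median fold enrichment was 66.1 for estradiol regions found in all 3 lists, 25.2 for those shared with LY500307 alone and 7.59 for those in no other list. Regions placed at random on the same chromosomes overlapped far less often: 0.709% of placed vehicle regions met an estradiol region. Each of the 6 directed overlaps had a permutation p of 0.000999, the smallest that 1000 placements can give. This p speaks only against uniform placement. It does not allow for the gathering of all 3 lists at promoters, so it cannot measure how alike the treatments are. The extent of sharing depended on how it was counted. With at least 50% of each region covered, a measure that also depends on region width, 44.3% of vehicle regions were shared with estradiol. By summits within 200 bp of each other, 79.9% of them were. With the 2905 strongest regions of each list, 87.7% of estradiol regions were in the LY500307 list and 47.7% in the vehicle list.

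**Figure D2:**
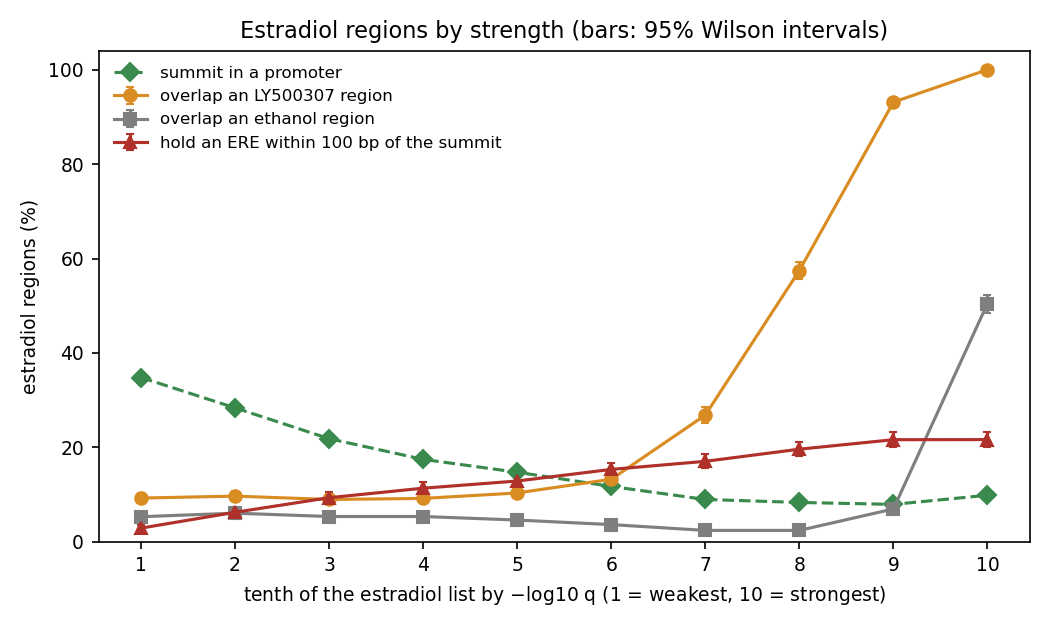
Percent of estradiol regions (y axis) that overlap an LY500307 region, overlap an ethanol region, hold an estrogen response element or lie in a promoter, by decile of the list in order of -log10 q (x axis, lowest to highest); bars on the points are 95% Wilson intervals and the dashed promoter line has none. Overlap with LY500307 stays between 8.97% and 13.3% up to the sixth decile and climbs to 100% in the highest.

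The sites with the highest -log10 q recurred across treatments. The estradiol region with the highest -log10 q lay in the promoter of ADAMTSL5, a gene for a secreted matrix protein, at chromosome 19, 1512727 to 1513914, with a fold enrichment of 196.5; the LY500307 region at this promoter had a fold of 135.2. A region in intron 2 of MYO18A, an unconventional myosin gene (chromosome 17, 29157946 to 29159354), had a fold of 178.7 with estradiol, 106.6 with LY500307 and 63.1 with vehicle. An intergenic region 40.1 kb from the transcription start site (TSS) of SMAD7, an inhibitor of TGF-beta signalling (chromosome 18, 48990702 to 48991825), had a fold of 176.9 with estradiol and 126.8 with LY500307. An intergenic region 27.7 kb from NTNG2, a gene for a netrin-like axon guidance protein, was among the 10 highest of every list, with folds of 175.2 with estradiol, 142.6 with LY500307 and 69.7 with vehicle. The other estradiol regions among the 10 highest lay near SPIN1, MANEAL, LAMC1, FOXK1, CSF2RB and SYNJ2, and all 10 overlapped a region in both other lists. With vehicle the highest -log10 q was at an intergenic region 52.5 kb from ABHD5, a lipolysis cofactor gene (chromosome 3, 43769856 to 43770486, fold 59.5), and the highest fold, 75.9, was at an intergenic region 10.6 kb from LAPTM4B (chromosome 8, 97764127 to 97764804).

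Strong ligand sites without a vehicle region lay near OPRL1, MITF, SERPINB9, FST and INHBB. The 10 highest estradiol regions that overlapped no vehicle region had folds of 99.0 to 128.8, and all 10 overlapped an LY500307 region. They included a region in intron 1 of OPRL1, the nociceptin receptor gene, which is also the promoter of RGS19, a regulator of G-protein signalling (chromosome 20, 64080329 to 64080957); the fold there was 122.9 with estradiol and 32.7 with LY500307. Intron 1 of MITF, the melanocyte transcription factor gene (chromosome 3, 69739385 to 69740099), had a fold of 121.1 with estradiol and 62.3 with LY500307. An intergenic region 28.0 kb from SERPINB9, a granzyme B inhibitor gene (chromosome 6, 2874964 to 2875638), had folds of 99.0 and 50.4 in the same order. The promoter of FST, which encodes the activin-binding protein follistatin (chromosome 5, 53479803 to 53480283), had a fold of 114.3 with estradiol, and an intergenic region 32.1 kb from INHBB, an activin subunit gene (chromosome 2, 120313786 to 120314356), had a fold of 128.8. The remaining estradiol regions of this group were nearest to ZBTB45, AKAP1, ARMC6, ARMC7 and ANKRD9. By nearest TSS, the remaining LY500307 regions without a vehicle region were assigned to ASPSCR1, COL18A1, DHX32, MRPS10, MYT1L, BRWD1 and ADAMTSL2. The MRPS10 one lay in intron 3 of TRERF1, 97.7 kb from the MRPS10 TSS, and the DHX32 one was also in the promoter of FANK1. The 10 highest LY500307 regions without a vehicle region all overlapped an estradiol region.

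The next comparison asked which DNA elements lay under the sites. The estrogen response element (ERE), the palindrome that estrogen receptors bind, was concentrated at the summits of all 3 lists. With at most 1 mismatch to GGTCANNNTGACC, it was present at 13.8% of estradiol summits (13.4 to 14.2), 15.7% of LY500307 summits (15.0 to 16.5) and 15.0% of vehicle summits (13.7 to 16.3). In windows 2000 bp downstream it was present at 0.644%, 0.687% and 0.689%. Intact copies without a mismatch included GGTCAGTGTGACC in the MANEAL promoter (chromosome 1, 37793146 to 37794000, estradiol fold 188.0) and GGTCACCTTGACC in intron 1 of FOXK1, a forkhead factor gene (chromosome 7, 4682522 to 4684274, estradiol fold 187.5). Of the 10 highest regions of each list, 6 held an ERE with estradiol, 2 with LY500307 and 2 with vehicle, and 2 of the 10 highest estradiol regions without a vehicle region held 1.

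Other elements were also more frequent at summits than downstream, and those of some lineage factors were less frequent. The downstream windows were not matched on base composition, and shuffled control sequence was used for the ERE alone. In the vehicle list, GATA elements were at 2.53% of summits shared with estradiol alone (median GC content 71.1%). They were at 20.7% of those shared with LY500307 alone (43.3%). Differences for AT-rich and GC-rich elements therefore cannot be told apart from base composition. The AP-1 element, bound by FOS and JUN proteins, was at 13.8% of estradiol summits against 3.43% of downstream windows, at 13.7% against 3.48% with LY500307, and at 10.4% against 3.51% with vehicle. GC-rich SP1 elements were at 11.5% of estradiol, 10.9% of LY500307 and 14.8% of vehicle summits, against 2.74%, 2.87% and 2.51% downstream. Elements of the TEAD factors, which act in the Hippo pathway, were at 16.3% of estradiol summits against 10.7% downstream. The element of FOXA, a pioneer factor of luminal breast cells, was less frequent at summits than downstream, at 2.75% against 5.56% with estradiol, 2.87% against 5.45% with LY500307 and 2.65% against 6.10% with vehicle. GATA elements were also less frequent, at 8.24% against 10.9% with estradiol.

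The tests were exact two-sided sign tests over regions, adjusted over 48 motif tests. For the ERE the exact test in the vehicle list gave p = 9.51e-108 (adjusted 3.51e-107); in the estradiol list 3680 regions had it at the summit alone and 146 downstream alone, and in the LY500307 list these counts were 1567 and 57. For FOXA the adjusted p was 3.18e-60 with estradiol, 6.33e-20 with LY500307 and 1.02e-10 with vehicle, and for AP-1 with LY500307 it was 5.89e-152. The ERE share rested on the mismatch allowed: without any mismatch it was 1.65% of estradiol, 1.84% of LY500307 and 2.38% of vehicle summits. With at most 2 mismatches it was 44.6%, 46.9% and 39.8% in the same order, against 7.80%, 7.68% and 8.16% downstream.

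**Figure D3:**
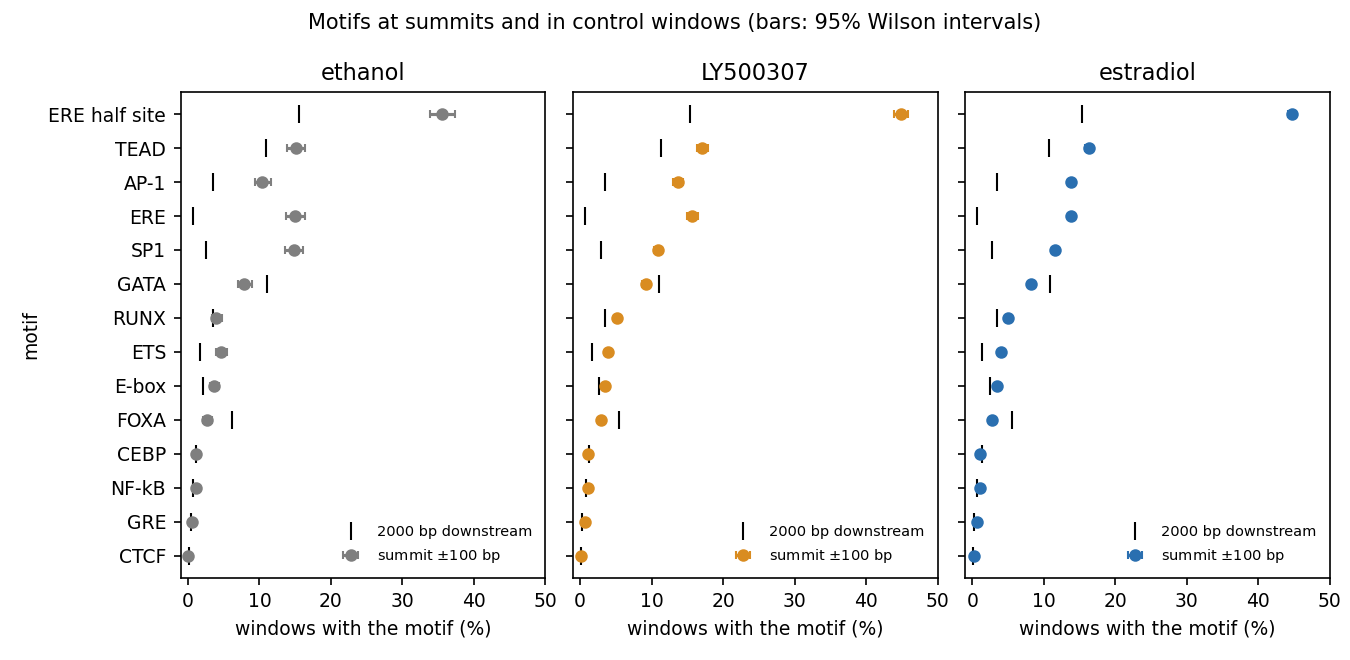
Percent of windows that hold each motif (x axis) at region summits (points with 95% Wilson intervals) and 2000 bp downstream (ticks) for the ethanol, estradiol and LY500307 lists. ERE points lie between 13.8% and 15.7% against downstream values under 0.7%, and FOXA points lie below their downstream values.

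Whether sites seen with several treatments were the ones with an ERE was asked within each list. LY500307 regions that overlapped no estradiol region almost never held an ERE: 6 of 815 did (0.736%, 0.338 to 1.60), against 1573 of 9228 (17.1%) of those that overlapped an estradiol region. Vehicle regions showed the same contrast, with 1 of 377 (0.265%) against 434 of 2527 (17.2%). The 5 highest LY500307 regions outside the estradiol list lay at HDAC7, a class IIa histone deacetylase gene (3 regions), in intron 6 of LDB2 (chromosome 4, 16511125 to 16511479, fold 11.4) and in intron 1 of WDR82 (chromosome 3, 52271983 to 52272348, fold 9.85); none held an ERE, and all overlapped a vehicle region. In the estradiol list the contrast was small, with an ERE at 17.4% of regions shared with LY500307 and at 12.0% of the others.

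Fisher's exact test, two-sided, gave odds ratios of 27.7 for LY500307 regions inside over outside the estradiol list (p = 1.91e-53, adjusted 9.55e-53 over 5 tests) and of 78.0 for vehicle regions (p = 2.53e-27). Within quartiles of -log10 q these odds ratios were 16.7 (7.41 to 37.7) and 45.0 (6.22 to 325.6). For estradiol regions shared with LY500307 the odds ratio of 1.55 (exact p = 3.57e-33, adjusted 8.92e-33) turned to 0.667 (0.597 to 0.745) within quartiles of -log10 q. In the lowest quartile an ERE was at 0.794% of the shared regions against 5.90% of the others. In the highest quartile the shares were close, at 21.45% and 23.76%. That quartile held 6092 of the 9080 shared regions and ran from a -log10 q of 50.7 to 841.5, so strength was not alike within it. Sharing with vehicle gave odds ratios of 1.36 in the estradiol list and 1.30 in the LY500307 list, and the odds ratios pooled within quartiles were 1.00 (0.891 to 1.13) and 1.14 (0.990 to 1.31). These pooled values hide opposite contrasts: in the lowest quartile of -log10 q an ERE was at 0 of the estradiol regions shared with vehicle against 5.75% of the others, and in the highest at 26.4% against 20.2%. In the LY500307 list the shares were 1.87% against 7.21% in the lowest quartile and 22.9% against 15.8% in the highest.

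The position of the summits relative to genes was compared with random placement. Promoters held 16.4% of estradiol summits (16.0 to 16.9), 14.0% of LY500307 summits (13.4 to 14.7) and 19.2% of vehicle summits (17.8 to 20.7), against 1.71%, 1.70% and 1.73% of placed regions. Introns held 41.9%, 43.2% and 41.1% of summits in the same order, close to the 42.3% of placed regions. Intergenic DNA held 35.0% of estradiol summits against 53.1% of placed regions. Weak estradiol regions were more often at promoters, with 34.8% in the lowest decile by -log10 q and 9.87% in the highest. Promoter enrichment had a two-sided permutation p of 0.002 in each list, the smallest that 1000 placements can give. A promoter defined as 2500 bp on both sides of the TSS held 33.8% of estradiol, 30.9% of LY500307 and 42.9% of vehicle summits.

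Gene groups fixed before the data were examined were then tested for a summit within 20 kb of a TSS, to ask which programmes lay near the enriched regions. Estrogen response genes were the group most often near an LY500307 site: 18 of 26 genes (69.2%) had one, against 28.1% of all 19663 protein-coding genes. This was the 1 group of 12 that passed the adjusted threshold, with an odds ratio of 5.77 (two-sided Fisher's exact p = 1.57e-05, adjusted 5.64e-04 over 36 tests). With estradiol 20 of the 26 genes had a site (76.9%, adjusted exact p = 0.0753), against 55.2% of all genes. With vehicle 8 had a site (30.8%, adjusted exact p = 0.0563), against 11.7% of all genes. All 18 genes with an LY500307 site also had an estradiol site. With LY500307 the group passed in every alternative setting for gene groups. With estradiol, but not vehicle, it passed within 5 kb of a TSS (odds ratio 4.86, adjusted Fisher's exact p = 0.0039). With vehicle, but not estradiol, it passed at -log10 q of 5 or more (adjusted Fisher's exact p = 0.0483) and at fold of 5 or more. Against matched random groups it passed in all 3 lists.

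Within this group, IGFBP4, which binds insulin-like growth factors, had a region in intron 1 (chromosome 17, 40448531 to 40449135) with the ERE GGTCAGAGTGCCC and a fold of 183.5 with estradiol, 112.7 with LY500307 and 30.9 with vehicle. RARA, a retinoic acid receptor gene, had a region in intron 1 (chromosome 17, 40321860 to 40322847) with folds of 180.0, 102.1 and 28.8 in the same order. An intergenic region 8.19 kb from CTSD, a lysosomal protease gene (chromosome 11, 1772404 to 1773050), had folds of 164.0, 75.9 and 19.6. GREB1, a cofactor of estrogen receptors, had an intronic region 16.4 kb from its nearest TSS (chromosome 2, 11498450 to 11499111) with folds of 105.2, 93.4 and 41.1. For TFF1, a secreted trefoil peptide and classical estrogen target, the strongest region lay 15.4 kb away in the promoter of the neighbouring trefoil gene TFF2, with a fold of 45.6 with estradiol and 10.4 with LY500307, and there was no vehicle region. MYC, a growth-promoting transcription factor gene, had 5 estradiol regions and none in the other lists. PGR, XBP1, STC2, EGR3, CXCL12 and AREG had no summit within 20 kb of a TSS in any list; within 100 kb, 24 of the 26 genes had an estradiol site.

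The other groups did not pass the adjusted threshold, and their members are given as values. Of 12 cystatin genes, which encode inhibitors of cysteine proteases, 7 had an estradiol site, 7 an LY500307 site and 4 a vehicle site. The promoter of CST5 (chromosome 20, 23879813 to 23880398) had folds of 147.7 with estradiol, 68.8 with LY500307 and 18.6 with vehicle, and CST3, CST1 and CST4 had estradiol folds of 132.5, 112.5 and 87.4. TGF-beta genes numbered 22 of 27 with estradiol, 10 with LY500307 and 2 with vehicle, and 14 of them had a site with estradiol alone. Intron 1 of SMAD3, the signal transducer (chromosome 15, 67109111 to 67109633), had folds of 133.6, 73.7 and 8.48 with estradiol, LY500307 and vehicle, and the promoter of SKIL, a repressor of SMAD proteins, had 52.7, 16.0 and 6.50. AP-1 family genes were near a site in 13 of 15 cases with estradiol and 9 with LY500307. The JUND promoter (chromosome 19, 18281577 to 18282139) had folds of 137.1, 65.7 and 18.9 (vehicle), and the strongest region near JUNB, 7.32 kb from its TSS and nearer to HOOK2, had 78.2 and 30.6 without a vehicle region.

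Genes of epithelial-mesenchymal transition and invasion had a site in 19 of 24 cases with estradiol, 11 with LY500307 and 7 with vehicle. They included LOX, a collagen crosslinking enzyme (estradiol fold 82.2), the promoters of the repressors SNAI2 (67.7) and SNAI1 (60.1), and AXL, a receptor tyrosine kinase (64.1). Cell cycle genes numbered 19 of 28, 11 and 7 in the same order, with estradiol folds of 76.4 in intron 1 of CCND1 and 71.5 at an intergenic region 5.90 kb from CDKN1B, a kinase inhibitor gene. The only region near CDK4 (fold 106.0) lay 15.5 kb from its TSS, in the promoter of EEF1AKMT3. NF-kB target genes numbered 16 of 25, 9 and 3, with estradiol folds of 104.5 near the cytokine gene LIF and 70.2 at the promoter of NFKBIA, the inhibitor of NF-kB. Nuclear receptor and coregulator genes numbered 19 of 26, 12 and 8, including the promoters of NCOA1 (112.0) and NR2F6 (79.1); 1 of the 8 with vehicle was ESR2 itself, counted for the region at its coding exon 2 that is described below. Of 12 genes of Polycomb repressive complex 2 and histone deacetylases, 11 had an estradiol site, 5 an LY500307 site and 2 a vehicle site, and the best fold was 43.5 near EED. No control group passed the adjusted threshold. Ribosomal protein genes had a site in 24 of 30 cases with estradiol (odds ratio 3.25, adjusted exact p = 0.0563) and 15 of 30 with LY500307 (odds ratio 2.56, adjusted exact p = 0.0563). Hepatocyte genes had an estradiol site in 11 of 20 cases (55.0% against 55.2% of all genes, adjusted exact p = 1), and neuron genes in 5 of 20 (odds ratio 0.270, adjusted exact p = 0.0563).

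The number of groups past the adjusted threshold was 0 for vehicle, 0 for estradiol and 1 for LY500307, whereas 6, 7 and 5 of the 12 had an unadjusted Fisher's exact p under 0.05. This count depended on the settings, since with sites within 5 kb of a TSS it was 2, 6 and 5, and against random groups matched on gene length and gene density it was 2, 5 and 4. Under both settings the ribosomal control group was among those counted for estradiol and LY500307, and the neuron control group was counted for estradiol because its genes had fewer sites.

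**Figure D4:**
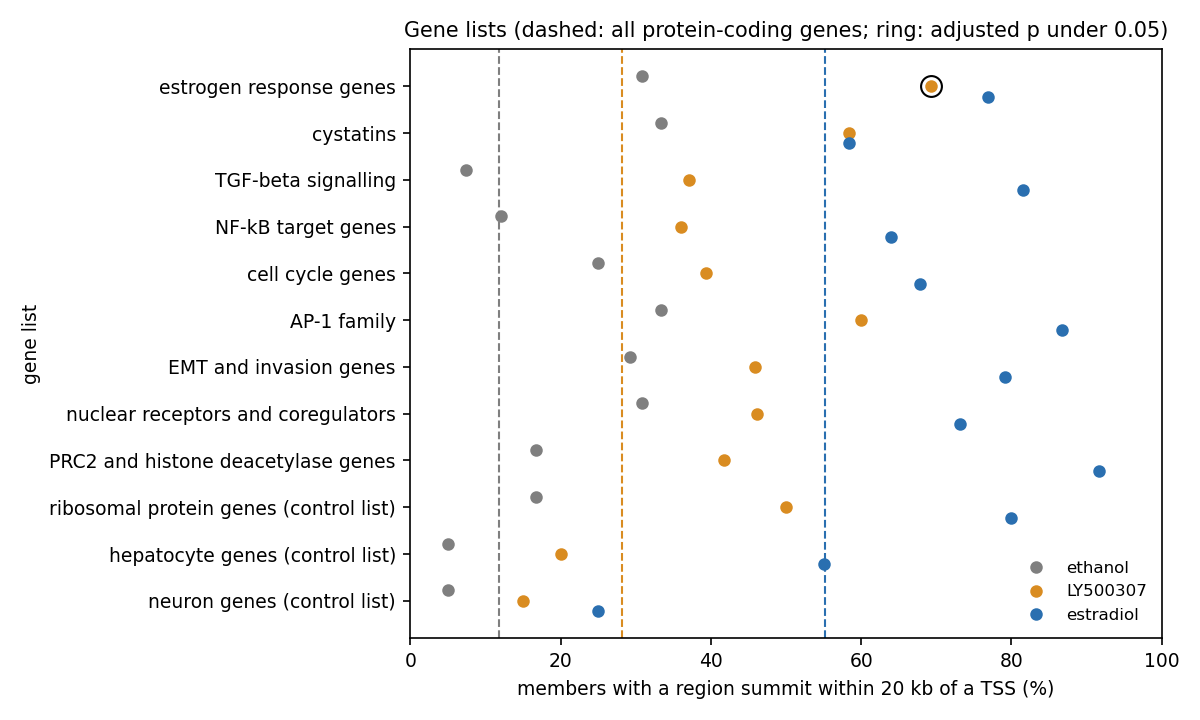
Percent of the members of each gene group with a region summit within 20 kb of a TSS (x axis) for each treatment's list; dashed lines give the percent of all protein-coding genes, and a ring marks an adjusted p under 0.05. Estrogen response genes with LY500307 carry the single ring, at 69.2% against 28.1% of all genes.

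ESR2, the gene of the expressed receptor, was examined in every list. Vehicle regions over ESR2 lay on its coding exons: all 7 summits within the coding span were in coding exons, which make up 3.19% of that span, and 7 of the 8 coding exons were touched. The strongest, at exon 2 (chromosome 14, 64282557 to 64283015), had a fold of 42.5 and no overlapping region with either ligand, and the region at exon 9 (64233104 to 64233379) had a fold of 15.0. With estradiol there were 2 regions over the examined ESR2 transcript, 1 in coding exon 8 (64234921 to 64235316, fold 31.9) and 1 in the untranslated part of exon 9 (64232503 to 64232863, fold 11.04). With LY500307 there were 2, both in coding exons. HDAC7 had the same arrangement: 12 of 13 vehicle, 7 of 9 LY500307 and 2 of 2 estradiol summits lay in coding exons. These make up 8.27% of its coding span, and 21 of its 26 coding exons were touched with vehicle. The vehicle region at exon 5 of HDAC7 (chromosome 12, 47797997 to 47798334, fold 12.7) and the LY500307 region spanning 47798466 to 47798989 (fold 14.7), whose summit lies in intron 3, were among the highest outside the estradiol list. One-sided exact binomial tests against the coding share of the span gave p = 3.36e-11 for ESR2 and 1.23e-12 for HDAC7 in the vehicle list, and 8.21e-07 for HDAC7 with LY500307; these tests were chosen after the positions were seen. No other gene had 4 or more vehicle summits in coding exons.

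**Figure D5:**
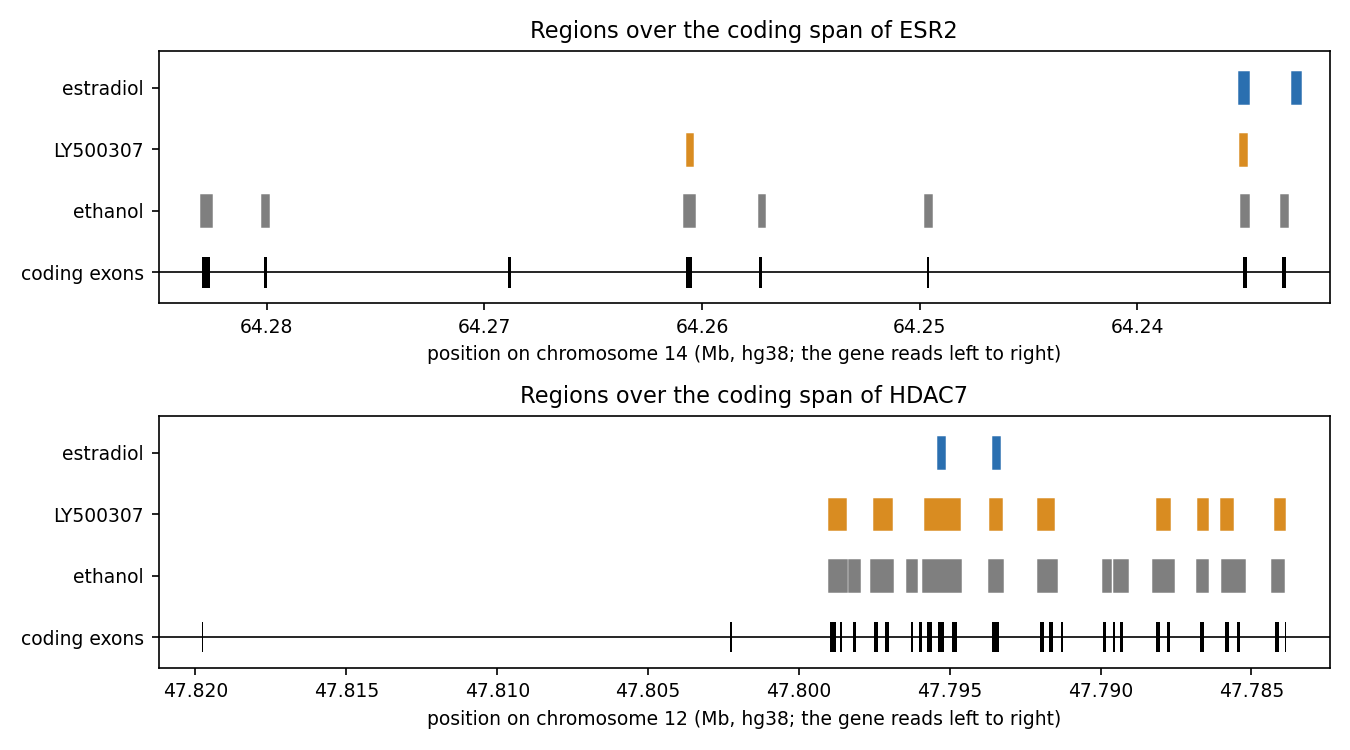
Enriched regions of the 3 lists along ESR2 on chromosome 14 and HDAC7 on chromosome 12 (x axis, position in Mb of hg38, drawn so that the genes read left to right), with the coding parts of exons as boxes. Untranslated parts are not drawn. In the vehicle list 7 of 7 summits in the coding span of ESR2 and 12 of 13 in that of HDAC7 lie in coding exons.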

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

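These counts were made after the data were seen. Some records lay on contigs outside chromosomes 1 to 22, X and Y, which no comparison used: 6 in the vehicle list, 35 in the estradiol list and 14 in the LY500307 list.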

How the results depend on the processing

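The ERE comparison outside promoters was chosen after the data were seen, and all other alternatives were planned. All 30 overlaps, 9 annotation values and 18 ERE shares under alternatives kept their direction and their side of the threshold. Region numbers carry no test and are counts only. Within quartiles of -log10 q, the odds ratio of an ERE in estradiol regions shared with LY500307 reversed to 0.667, and those for regions shared with vehicle fell short of the threshold at 1.005 in the estradiol list and 1.139 in the LY500307 list. The number of gene groups past the adjusted threshold, which was 0 for vehicle, 0 for estradiol and 1 for LY500307, moved to 4, 3 and 3 with -log10 q of 5 or more, and to 4, 2 and 3 with fold of 5 or more. With 5 kb it was 2, 6 and 5. With 100 kb it was 1 for vehicle, and against 10000 matched random groups it was 2, 5 and 4. The ribosomal control group is among those counted for estradiol or LY500307 in all of these settings but 100 kb. In the same settings the vehicle counts include nuclear receptor and coregulator genes, where ESR2 itself is a member with a site. The cause was not tested for any of these. Of the 36 tests of a single gene group in a list, 18 passed the threshold in no setting. In the other 18, 40 of 90 values passed under an alternative without doing so in the reported setting. No paired analysis was possible because each treatment has 1 pooled list. For the same reason no result could be computed without a single library.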

Other observations

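The tests on classes of regions, the coding-exon share, its binomial test and the coding length of exons, the background pileup, the deciles of the estradiol list and the ERE comparison outside promoters were chosen after the data were seen. LY500307 regions found in neither other list often held the purine-rich word AGGGAGA, which lay at 22.4% of these 671 summits against 7.70% of all other LY500307 summits. The word was noticed among all words of 7 bases for its excess at the summits of this and other classes, so these shares are not a test. When the word with the largest excess was picked anew from the regions of this class on odd-numbered chromosomes, it was again AGGGAGA. On the other chromosomes it lay at 24.7% of 316 summits (20.2 to 29.7) against 4.75% of downstream windows (exact two-sided sign test p = 2.71e-12). The split was made after the word had been seen on all chromosomes, so it guards against the choice among words but was not blind. Vehicle regions shared with LY500307 but not with estradiol had the word at 28.3% of 145 summits against 5.52% downstream, and 0 of the 145 held an ERE.

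Estradiol regions shared with vehicle but not with LY500307 were more often at promoters, although most lay elsewhere. Promoters held 43.6% of these 337 summits against 16.1% of the others (odds ratio 4.04, adjusted Fisher's exact p = 1.32e-31 over 6 tests; 2.51 within quartiles), and SP1 elements 26.4% against 11.3% (odds ratio 2.81, adjusted p = 8.51e-14; 2.02 within quartiles). An ERE was at 1.78% of them. Their median GC content was 69.65%, against 54.23% to 56.72% in the other classes of estradiol regions. The SP1 difference therefore cannot be told apart from base composition or promoter position. Among estradiol regions in no other list, AP-1 elements were at 13.5% of summits against 14.5% of the others (odds ratio 0.922, adjusted exact p = 0.0346). That odds ratio reversed to 1.86 (1.66 to 2.09) within quartiles, and the one for promoters went from 1.18 to 0.487 (0.445 to 0.533).

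Vehicle regions over ESR2 and HDAC7 followed coding exons. With estradiol, 1 of the 2 regions over ESR2 lay in the 3' UTR, and 2 of 2 summits in the coding span of HDAC7 lay in coding exons. DNA that holds exons without introns, such as a cDNA in an expression construct, is a candidate explanation, but the 92.3% of vehicle summits of HDAC7 in coding exons prompted it and cannot support it. Binding spread along HDAC7 without regard to exons would rarely give this share. The exact binomial p stayed at 2.42e-08 after multiplication by the 19663 genes among which HDAC7 was noticed. That multiplication does not cover the choice of coding exons as the feature, which the same positions prompted. The p therefore describes the pattern and is not separate evidence against such binding. Binding at the exons themselves also stays open. The 5 HDAC7 exons without a vehicle region had shorter coding parts (mean 54.8 bp against 128.5 bp, two-sided permutation p = 6.99e-04), which loss of short exons would give, although longer parts are also more often met by chance; whole exon lengths (302.8 bp against 128.5 bp, permutation p = 0.371) decide nothing because the last exon is mostly untranslated. ESR2 is the expressed transgene, whereas no label names an HDAC7 construct, so its source was not tested.

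The estradiol list was longer than the LY500307 list. Deeper sequencing of the estradiol pool is argued against by its background pileup of 1.0 fragments, the lowest of the 3 lists. The ratio of region numbers was still 2.68 or more under both stricter thresholds. This argues against regions with a -log10 q or fold under 5 as the source of the difference. These thresholds kept most regions, with 25234 of 26861 estradiol and 9411 of 10045 LY500307 regions left at -log10 q of 5 or more. They cannot decide about weak regions as a whole, since estradiol regions in no other list had a median fold of 7.59. A less efficient precipitation in the LY500307 pool and a weaker or less potent ligand response cannot be told apart, since both would lose the weak sites first and 9.27% of the lowest decile of estradiol regions were in the LY500307 list. The uncertain LY500307 dose may add to this difference and was not tested.

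LY500307 regions outside the estradiol list rarely held an ERE. Their lower strength does not account for this, because the odds ratio was 16.7 within quartiles of -log10 q. Signal at promoters does not either, since the odds ratio outside promoters was 30.4. Signal that does not depend on receptor binding to an ERE is a hypothesis that stays open, and no biological explanation was tested.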
